A study of Homo sapiens with 6 samples.

How the data were processed

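The series measured poly(A) RNA of CAL-51 breast carcinoma cells sorted on a p27-mVenus reporter after transfection of a plasmid, with 3 libraries of p27-positive and 3 of p27-negative cells. Libraries were made with a stranded kit for poly(A) RNA, per the labels' protocols. STAR, featureCounts and DESeq2 are named in the submitters' processing notes, with build hg38. Their versions, the annotation release, the strand setting of the counting and the mapping filters are not given in the sources used here. Overlapping genes, and genes on opposite strands of the same place, are therefore treated as uncertain.

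Both deposited tables hold the same 22794 genes, each with a symbol or identifier, a type, a position and a value in each of 6 libraries. The signal in the first table is a read count per gene divided by a DESeq2 size factor per library by the authors, per the file headers. The second table holds FPKM values made by the authors, per the file headers. Every normalized count was a whole multiple of 1 step per library within a tolerance of 1e-06 (100% of values), so the whole reads were recovered, and no gene had a total below 10 reads over the 6 libraries. The recovered totals were 22216934 to 28609257 reads per library, and the relative depths read from the FPKM values above 0 matched these totals. No column of a sample outside the series was found. The name column repeats the identifier for 4307 genes, and 45 symbols belong to more than 1 gene and were not used by symbol.

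The main test was planned for normalized values. It was limma 3.58.1 in R 4.3.3 with a trended prior, two-sided, on log2(normalized count + 1), for the 15950 genes with a mean normalized count of at least 10 over all 6 libraries, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values in the text are from limma or, for gene lists, from limma's camera, unless another tool is named. The prior had 34.6 degrees of freedom. edgeR 4.0.16 gave a biological coefficient of variation of 0.0855, which is low. Gene lists were tested with camera at an inter-gene correlation of 0.01 where at least 5 members were tested, with Benjamini-Hochberg adjustment over lists. Camera compares a list with all other genes. It was repeated with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and compares them with no other genes. Members were also counted after adjustment over the list alone.

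The test and its alternatives, the rule for named genes and 31 gene lists were fixed before the data were examined. The lists cover quiescence-associated transcripts, cell cycle inhibitors and G0 regulators, G1/S and G2/M genes, TRPC and store-operated calcium entry, calcium-dependent signalling, ferroptosis defence and promotion, integrins and laminins, mesenchymal genes and matrix, epithelial genes, mammary basal and luminal markers, cholesterol and SREBP2 genes, p53 targets, interferon-stimulated genes, NF-kB and inflammatory cytokines, immediate early genes, heat shock proteins, ATF4 targets, endoplasmic reticulum chaperones, hypoxia and glycolysis, lysosome and autophagy, nuclear-encoded oxidative phosphorylation, mitochondrial-encoded genes, ribosomal proteins, ribosome biogenesis and MYC targets, replication-dependent histones, breast stem cell and drug tolerance markers, leukocyte markers, and endothelial and stromal markers. The named genes are CDKN1B, TRPC6, GPX4, SLC7A11 and ACSL4, the 10 largest increases and 10 largest decreases among called genes with a mean of at least 50 normalized counts and no overlap between groups, leaving out unnamed loci, and up to 4 members of each list with the smallest p. Members that make up a count of 5 or fewer, CCNE1, NUSAP1, PMVK, CD63, DMXL1, PTPRC, PDGFRA, TRPC1, TRPV1, TRPV2, TRPV4, TRPM4, TRPM7, ORAI1, ORAI2, STIM1 and STIM2, and genes read in a single group, were chosen after their values were seen. Some genes are not reported here. A further 6 lists were written after the gene table was seen and are reported in the closing section only.

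Alternatives were a pseudocount of 0.5 or 5, no expression filter or a minimum of 50, quantile normalization, upper-quartile rescaling, the FPKM table with log2(FPKM + 0.1) and a mean of at least 0.5, no trended prior, the replicate number as a block, edgeR's quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. Scaling to the library total was added after the data were seen. On recovered reads, lists were tested with camera on edgeR's model and on the statistics of DESeq2. There edgeR called 8290 genes and DESeq2 8174, against 8385 with limma. TRPC6 fell below the filter, so its reads were compared with an exact binomial interval at 95% confidence, an exact permutation test of the libraries and fits without the filter. The exact binomial interval covers counting error only. For genes read in a single group, a floor of 3 counts was set for the other group. That floor takes the reads of the first group as exact, so the fold is no strict lower bound.

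The procedure was tested on simulated data with 15643 genes drawn from the real means and depths. It recovered 25% of genes changed by 0.25 on the log2 scale, 42% at 0.5, 80% at 1 and 96% at 2, and called 0.0454% of unchanged genes, which made up 4.76% of its calls. Few genes were changed in the simulation and 147 were called, against 8385 in the real data, so its cut-off on unadjusted p was stricter. These recovery rates therefore do not give the power of the real test. Camera called 0 of 30 unchanged lists of 30 genes. The simulated genes varied independently, so this does not test camera on lists whose members vary together. The estimated correlation of the real ribosomal protein list, for example, was 0.29. Permutation tests, intervals and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Positions are those of the deposited tables, and 21515 of their identifiers were found in GENCODE 29, of which 21496 lay on the same chromosome and near the same start.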

Results

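Poly(A) RNA of CAL-51 cells, an established human breast carcinoma line, was profiled after transfection with a plasmid carrying a p27-mVenus reporter and sorting on the reporter. p27 is the cyclin-dependent kinase inhibitor encoded by CDKN1B, which holds cells before S phase. The series holds 3 libraries of p27-positive and 3 libraries of p27-negative cells. The p27-positive libraries held 23297719, 24033087 and 26735554 reads assigned to listed genes, and the p27-negative libraries held 28609257, 22894616 and 22216934 reads. Values below are mean normalized counts ± SD over the 3 libraries of a group, and log2 fold changes ± SE are p27-positive minus p27-negative on the scale of log2(normalized count + 1), which understates the change of low genes. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The 6 pairs of libraries within a group differed by more than counting noise, with a chi-square of 5.14 to 6.27 per degree of freedom, against 83.0 to 104 for the 9 pairs across groups.

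The comparison asked which transcripts accompanied a high or low p27 reporter. By the sort the p27-positive cells hold the plasmid, and mock-transfected libraries are not analysed here. A response to the plasmid or its product therefore cannot be told apart from p27 state for any gene or list below. The p27-positive cells had far lower levels of the genes of DNA replication and mitosis and higher levels of p53 targets, cholesterol genes, epithelial genes and inflammatory cytokine genes. MKI67, the gene of the proliferation marker Ki-67, was 3.44-fold lower (6153 ± 170 against 21160 ± 410), and CDKN1A, which encodes the kinase inhibitor p21, was 3.71-fold higher (9995 ± 398 against 2692 ± 140). SCD, the desaturase that makes monounsaturated fatty acids, was 10.5-fold higher (25689 ± 120 against 2444 ± 94.2). CCN2, a secreted matricellular factor, was 13.3-fold lower (412 ± 44.9 against 5463 ± 268).

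Of 15950 genes tested with limma, 4067 rose and 4318 fell at a Benjamini-Hochberg adjusted p under 0.05. Large changes were mostly increases, with 1484 genes higher and 463 lower at least 2-fold (76.2% increases). With quantile normalization, which gives every library the same distribution, 909 were higher and 745 lower (54.96% increases). The groups did not overlap in 9200 genes (57.7%), against 10% by chance for 3 against 3. The share of increases among called genes depended on scaling. It was 48.5% with the authors' size factors, 63.2% with scaling to the library total (5343 higher, 3114 lower), 61.1% with upper-quartile rescaling (5142 higher, 3267 lower) and 59.4% in the FPKM table (4145 higher, 2832 lower). Scaling to the library total moved the median log2 fold change of all tested genes by 0.13 and upper-quartile rescaling by 0.11, so changes of that size are relative to the authors' scaling. The 1st principal component held 55.2% of the variance and separated the groups. The 2nd held 14.4% and set p27-negative replicate 3 (53.9) apart from p27-negative replicates 1 (-28.6) and 2 (-24.5), and without that library 8074 genes were called.

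Among genes with a mean of at least 50 normalized counts, the largest increases were in genes of low level in p27-negative cells. MUC19, a gel-forming mucin gene, rose from 4.82 ± 4.59 to 137 ± 26.4 normalized counts (log2 fold change 5.09 ± 0.62). SCN2A (4.26 ± 0.48), a neuronal sodium channel gene, PLEKHB1 (4.25 ± 0.42), SPTLC3 (4.15 ± 0.52), which encodes a serine palmitoyltransferase subunit, and the sterol carrier gene STARD4 (4.12 ± 0.29) followed. ABAT (4.12 ± 0.31), MAPK10 (4.11 ± 0.66), the phospholipase gene PLA2G3 (4.05 ± 0.23), IFIT2 (3.93 ± 0.67) and the kinase gene FRK (3.92 ± 0.40) completed the 10 largest increases. The largest decreases were in CCN2 (-3.73 ± 0.07), CCN1 (-2.90 ± 0.06) and ANKRD1 (-2.55 ± 0.14), which are widely used readouts of YAP and TEAD transcription. They were followed by PRC1 (-2.35 ± 0.44), the orphan receptor gene GPR3 (-2.23 ± 0.23), the immediate early gene EGR1 (-2.21 ± 0.17), the kinetochore gene SPC25 (-2.09 ± 0.11), AURKB (-1.99 ± 0.08), CCNA2 (-1.98 ± 0.05) and CENPA (-1.94 ± 0.12). PRC1 shares its strand and position with another listed gene, so its low count is uncertain. Each of these 20 genes had an adjusted p of 1.8e-05 or less by limma with Benjamini-Hochberg adjustment. IFIT2 lost its call without the trended prior (adjusted p = 0.054 by limma), and had no reads in p27-negative replicate 2, without which its log2 fold change was 2.53. MAPK10 had no reads in p27-negative replicate 3, without which it was 2.69. The log2 fold change of MUC19 was 4.09 without p27-negative replicate 2, where it had no reads, that of SCN2A 3.35 without p27-negative replicate 1 and that of PLEKHB1 3.52 without p27-negative replicate 3.

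**Figure D1:**
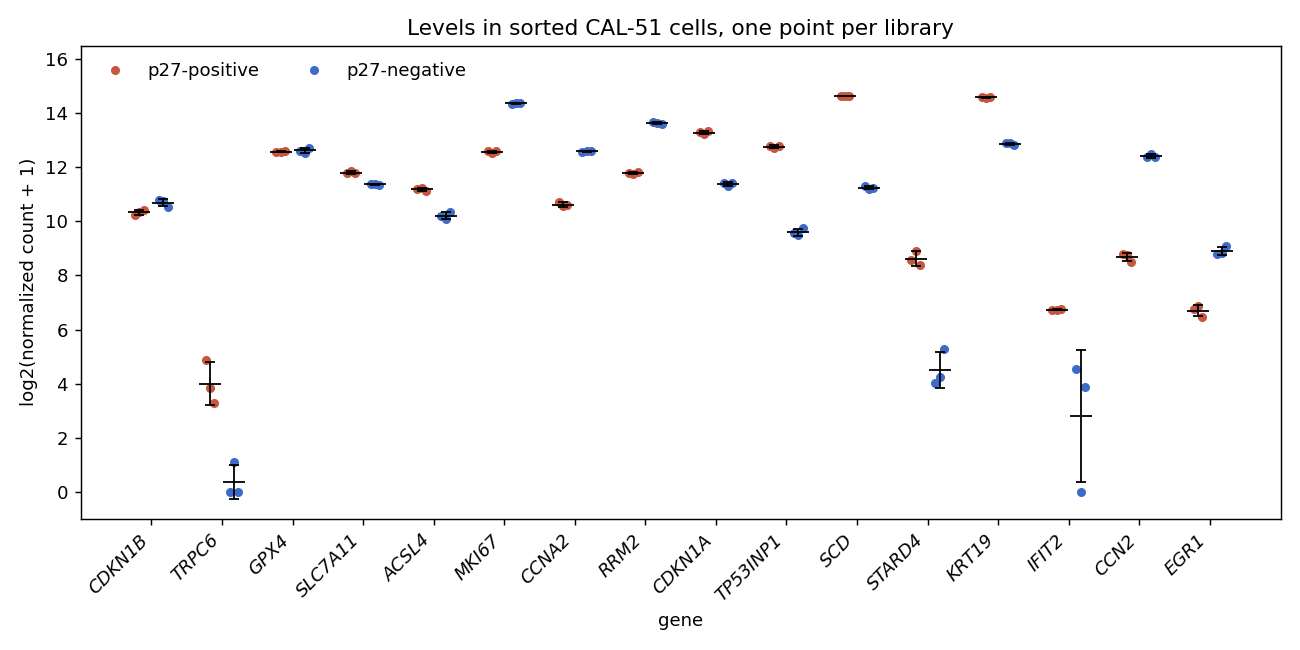
Levels of 16 genes in each library as log2(normalized count + 1) on the vertical axis, with p27-positive libraries in red and p27-negative libraries in blue. Black bars give the mean and SD of 3 libraries on that log2 scale. GPX4 lies level in both groups (6135 and 6341 normalized counts), while SCD lies 10.5-fold higher and CCN2 13.3-fold lower in p27-positive cells.

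CDKN1B mRNA was lower in the cells sorted as p27-positive. The gene (chromosome 12, 12685498 to 12722369, build hg38 per the submitters' processing notes) had 1295 ± 75.4 normalized counts in p27-positive and 1659 ± 153 in p27-negative libraries, a log2 fold change of -0.35 ± 0.07 (limma, adjusted p = 6.8e-05), lower in 3 of 3 libraries. The sort was on the reporter protein, and reads from the plasmid could not be separated from those of the endogenous gene. In the FPKM table the log2 fold change was -0.22 ± 0.09 and did not pass (limma, adjusted p = 0.069).

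TRPC6, the receptor-operated calcium channel gene named in the series title (chromosome 11, 101451564 to 101872562), was read almost only in p27-positive cells. The 3 p27-positive libraries held 28, 14 and 10 reads and the p27-negative libraries 0, 1 and 0. The ratio of the 52 to the 1 read, after size factors, was 47.3, with an exact 95% counting interval of 8.12 to 1903 that covers counting error only. The gene fell below the expression filter, at 16.8 ± 10.2 against 0.371 ± 0.642 normalized counts. An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest that design allows. Without the filter the adjusted p was 0.0024 by limma, and on recovered reads 0.0014 by edgeR and 0.00067 by DESeq2. Genes of low level leaned this way in general, with 303 of the 6844 genes below the filter called higher and 59 lower by limma without it, and 291 genes read in every p27-positive and no p27-negative library against 48 of the reverse kind.

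The other channels and pumps of the list of TRPC and store-operated calcium entry went both ways. Of 20 tested members 8 rose and 6 fell (8 and 6 adjusted over the list alone), and the list did not pass camera (median log2 fold change 0.30, adjusted p = 0.20). Scaled to the library total 11 rose and 3 fell, and the median was 0.14 without p27-negative replicate 2 and 0.024 with a minimum of 50 normalized counts. ATP2B4, a plasma membrane calcium pump gene, rose (0.97 ± 0.04), as did the inositol trisphosphate receptor gene ITPR2 (1733 ± 87.3 against 867 ± 31.3 normalized counts), while ITPR3 (-0.39 ± 0.07) and the reticulum pump gene ATP2A2 (-0.25 ± 0.03) fell. The ATP2A2 call was lost with quantile normalization, and the ITPR3 call was lost in the FPKM table. The TRP channel gene TRPC1 rose by 0.89, TRPV1 by 1.13, TRPV2 by 1.90, TRPV4 by 1.60 and TRPM4 by 0.74. TRPM7 (0.02) did not pass, and no TRP channel gene of the list fell. TRPV2 had few reads, 107 in p27-positive and 29 in p27-negative libraries. Among genes of store-operated entry ORAI2 (-0.27 ± 0.07) and STIM2 (-0.42 ± 0.09) fell while ORAI1 (0.08) and STIM1 (0.02) did not pass. In the list of calcium-dependent signalling, 6 of 22 rose and 8 fell (6 and 8 adjusted over the list alone). The calmodulin genes CALM2 (-0.79 ± 0.03) and CALM3 (-0.38 ± 0.04) fell, and the kinase gene CAMK2D rose (0.68 ± 0.10). That list did not pass camera (adjusted p = 0.58), with a median of -0.01, a mean of 0.12 and a downward test against the other genes. Scaled to the library total 7 of these genes rose and 6 fell, with a median of 0.13, while with quantile normalization the median was -0.12.

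The genes of ferroptosis, an iron-dependent death by lipid peroxidation, went both ways. GPX4 (chromosome 19, 1103982 to 1106791), which reduces lipid hydroperoxides, was at 6135 ± 98.5 against 6341 ± 395 normalized counts (-0.05 ± 0.04; limma, adjusted p = 0.39), and its sign turned under the 4 other scalings, from 0.07 with upper-quartile rescaling to 0.12 with quantile normalization, where it passed (limma, adjusted p = 0.015). SLC7A11 (chromosome 4, 138164097 to 138242349), the cystine importer, rose by 0.44 ± 0.05 (limma, adjusted p = 9.2e-10). ACSL4 (chromosome X, 109624244 to 109733403), which loads polyunsaturated fatty acids into phospholipids, rose by 0.97 ± 0.07 (limma, adjusted p = 2.5e-15). Of 35 tested defence genes 8 rose and 14 fell (8 and 15 adjusted over the list alone). The risers SCD (3.39 ± 0.04), DHCR7 (2.43 ± 0.08) and FADS2 (2.17 ± 0.07) are lipid and sterol enzymes, and NQO1 (-0.78 ± 0.04), an NRF2 target, fell. The places of DHCR7 and FADS2 in the defence list are uncertain, so the counts, mean and tests of that list are not a measure of defence. Of 29 promotion genes 11 rose and 10 fell (11 and 11 adjusted over the list alone), with SAT1, a polyamine acetyltransferase gene, at 2.32 ± 0.08, FADS1 at 0.67 ± 0.05 and VDAC3 at -0.56 ± 0.05. By contrast, with scaling to the library total 12 defence genes rose and 10 fell, and 13 promotion genes rose and 5 fell. Neither list passed camera (adjusted p = 0.85 and 0.54), while fry, which makes no comparison with other genes, called both upward (adjusted p = 0.0033 and 0.0082). The defence list had a median of -0.07 and a mean of 0.13 with a downward test, and the promotion list a median of -0.04 and a mean of 0.22 with an upward test. The promotion median ran from -0.073 without p27-negative replicate 3 to 0.039 without p27-negative replicate 1, and was 0.015 without p27-negative replicate 2. The list of ferroptosis defence passed upward with DESeq2 (adjusted p = 0.041) and that of ferroptosis promotion with quantile normalization (adjusted p = 0.040).

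Cell cycle genes fell almost without exception. Of 50 G2/M genes 49 fell and none rose, with a median of -1.60, and NUSAP1 did not pass. MKI67 (chromosome 10, 128096659 to 128126423) changed by -1.78 ± 0.03, CENPF by -1.64 ± 0.04, the spindle gene TPX2 by -1.61 ± 0.04 and the topoisomerase gene TOP2A by -1.58 ± 0.04. Of 46 G1/S genes 45 fell, with a median of -1.25. Among them RRM2 (-1.84 ± 0.04) and RRM1 (-1.33 ± 0.05), the subunits of ribonucleotide reductase, and the helicase genes MCM7 (-1.36 ± 0.04) and MCM4 (-1.29 ± 0.04) fell. CCNE1, the cyclin that drives entry into S phase, was the exception and rose by 0.67. Adjusted over the list alone, 49 G2/M genes and 45 G1/S genes fell. Both lists passed camera (adjusted p = 1.6e-47 and 1.4e-32), and with an estimated correlation (adjusted p = 0.021 and 0.025).

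Inhibitors of the cycle went both ways. Of 22 tested inhibitors and G0 regulators 9 rose and 8 fell (9 and 8 adjusted over the list alone), and the list did not pass camera (median 0.17, or -0.018 without p27-negative replicate 2, adjusted p = 0.91), while fry called it upward (adjusted p = 0.0081). CDKN1A (chromosome 6, 36676460 to 36687337) rose by 1.89 ± 0.05, the antiproliferative gene BTG2 by 2.37 ± 0.06 and FOXO4 by 2.14 ± 0.15, while the pocket protein gene RBL1 fell (-1.34 ± 0.07). Among transcripts associated with quiescence 21 of 23 rose and none fell (21 adjusted over the list alone), with a median of 0.65. They included the saposin precursor gene PSAP (1.15 ± 0.03), the actin-severing gene GSN (1.62 ± 0.05), TXNIP (1.03 ± 0.08) and CST3 (0.65 ± 0.05), and CD63 and DMXL1 did not pass. Of 30 p53 targets 26 rose, with a median of 0.99, and PLK2 fell (27 and 1 adjusted over the list alone). TP53INP1 rose 8.96-fold (3.16 ± 0.06) and ZMAT3 by 1.23 ± 0.05. The quiescence and p53 lists passed camera (adjusted p = 4.5e-11 and 1.1e-17), and with an estimated correlation (adjusted p = 0.038 and 0.025).

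Genes of cholesterol synthesis rose together. Of 24 tested genes of the pathway and its regulator SREBP2, 23 rose and none fell (23 adjusted over the list alone), with a median of 1.44, and PMVK did not pass. MSMO1 (2.58 ± 0.07) and DHCR7 (2.43 ± 0.08), late steps of the pathway, HMGCS1 (2.08 ± 0.05), an early step, and the regulator gene SREBF2 (1.56 ± 0.04) rose. The list passed camera (adjusted p = 1.0e-23), and with an estimated correlation (adjusted p = 0.016). Genes of lysosome and autophagy rose by less, 24 of 39 with 6 lower (24 and 6 adjusted over the list alone) and a median of 0.23. The acid glucosidase gene GAA (1.19 ± 0.09), the cholesterol exporter gene NPC1 (0.78 ± 0.07), ATG2A (0.63 ± 0.07) and the sialidase gene NEU1 (0.62 ± 0.06) led that list by p. With scaling to the library total the median was 0.36, with 26 higher and 2 lower. It passed camera (adjusted p = 8.4e-04), and with an estimated correlation (adjusted p = 0.045).

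Interferon-stimulated and inflammatory genes were higher in p27-positive cells. Of 30 tested interferon-stimulated genes 21 rose and 3, OAS3 and IFIT5 among them, fell (21 and 3 adjusted over the list alone), with a median of 1.02. TRIM22 rose by 1.78 ± 0.07, the transcription factor gene STAT2 by 1.07 ± 0.09, PARP14 by 0.69 ± 0.05 and PARP9 by 0.66 ± 0.07. The 3 members that fell did not fall with scaling to the library total, where 22 rose and 0 fell. The list passed camera with the preset correlation (adjusted p = 1.1e-04), a call lost with an estimated one (adjusted p = 0.11 with an estimated correlation). Of 27 genes of NF-kB and inflammatory cytokines 15 rose, with a median of 0.76, and NFKBIE and SOD2 fell (15 and 2 adjusted over the list alone). The chemokine genes CXCL3 (1.75 ± 0.18) and CXCL8 (1060 ± 41.6 against 531 ± 22.5 normalized counts) and the TNF-induced genes TNFAIP3 (1.32 ± 0.08) and TNFAIP2 (1.10 ± 0.04) rose. With scaling to the library total 18 rose and 0 fell, and with a minimum of 50 normalized counts the median was 0.29. That list passed camera (adjusted p = 5.6e-04), and with an estimated correlation (adjusted p = 0.045).

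Genes of ribosome building fell. Of 40 tested genes of ribosome biogenesis and MYC targets 35 fell, with a median of -0.55, and NOP53 rose (37 fell and 1 rose adjusted over the list alone). ODC1, the first enzyme of polyamine synthesis, fell by 1.20 on the log2 scale, the nucleolar genes NCL and NPM1 were at -0.86 ± 0.02 and -0.86 ± 0.03, and the mitochondrial chaperonin gene HSPD1 at -0.79 ± 0.03. The list passed camera (adjusted p = 1.4e-16), and with an estimated correlation (adjusted p = 0.025). Of 78 ribosomal protein genes 57 fell and 3, RPS19, RPL37 and RPL13A, rose (58 and 3 adjusted over the list alone), with a median of -0.18. RPS16 (-0.44 ± 0.04), RPSA (-0.40 ± 0.03), RPS27A (-0.38 ± 0.03) and RPL14 (-0.35 ± 0.03) led by p. Many such genes share sequence with pseudogenes, so their counts are uncertain. Camera called the ribosomal protein list (adjusted p = 1.1e-08), a call that was lost (adjusted p = 0.28 with an estimated correlation) and with quantile normalization (adjusted p = 0.84). With scaling to the library total the median was -0.05, with 14 members higher and 30 lower.

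Respiratory chain genes changed little. Of 57 nuclear-encoded genes of oxidative phosphorylation 30 fell and 4, NDUFA13, COX5B, COX7C and COX6B1, rose (32 and 4 adjusted over the list alone), with a median of -0.21. The cytochrome genes CYC1 (-0.48 ± 0.04) and CYCS (-0.38 ± 0.04) and the ATP synthase genes ATP5F1C (-0.39 ± 0.05) and ATP5F1B (-0.30 ± 0.03) fell. Camera called the nuclear-encoded list (adjusted p = 0.0055), a call that was lost (adjusted p = 0.29 with an estimated correlation). It did not pass with scaling to the library total (adjusted p = 0.098), where 14 rose and 20 fell, nor with quantile normalization, upper-quartile rescaling, the FPKM table, edgeR or DESeq2. Of 13 mitochondrial-encoded genes 8 fell and 3, MT-ND5, MT-ND3 and MT-ND6, rose (8 and 3 adjusted over the list alone), with a median of -0.20 and no pass in camera (adjusted p = 0.088). MT-ND4L (-0.40 ± 0.03), MT-CO2 (-0.31 ± 0.04), MT-ND2 (-0.28 ± 0.04) and MT-ND4 (-0.25 ± 0.03) fell, and with scaling to the library total 5 of the 13 rose and 6 fell. The calls of MT-CO2, MT-ND2 and MT-ND4 were lost in the FPKM table. The mitochondrial-encoded list passed camera without p27-positive replicate 3 (adjusted p = 9.5e-04) or p27-negative replicate 1 (adjusted p = 0.015), and without the expression filter (adjusted p = 0.022). Mitochondrial reads were 4.05% ± 0.256 of reads assigned to listed genes in p27-positive and 3.82% ± 0.212 in p27-negative libraries. That share is of the library total, not scaled by size factors, and includes mitochondrial ribosomal RNA. The ribosomal RNA alone was 0.584% to 0.615% in p27-positive and 0.412% to 0.441% in p27-negative libraries.

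Epithelial and adhesion genes rose. Of 23 tested epithelial genes 15 rose, with a median of 0.97, and EPCAM fell (15 and 2 adjusted over the list alone). The keratin gene KRT19 rose from 7546 ± 189 to 24864 ± 349 normalized counts (1.72 ± 0.03), the epithelial transcription factor gene ELF3 by 2.18 ± 0.16, the plakoglobin gene JUP by 0.97 ± 0.05 and KRT8 by 0.60 ± 0.02. With scaling to the library total 16 rose and 0 fell. Of 24 integrin and laminin genes 16 rose, with a median of 0.30, and ITGA9 and ITGB1 fell (17 and 3 adjusted over the list alone). LAMA3 (1.40 ± 0.10) and LAMB2 (0.96 ± 0.04), chains of basement membrane laminins, rose with the laminin receptor gene ITGA6 (1.38 ± 0.04). Both lists passed camera (adjusted p = 1.1e-05 and 1.0e-04), and with an estimated correlation (adjusted p = 0.033 and 0.038). The luminal list held 18 markers and the basal list 16, and 8 of each were tested. KRT19 and KRT8 stand in both the luminal and the epithelial list. Of the 8 luminal markers 6 rose, with a median of 0.66, and ERBB3 fell (7 and 1 adjusted over the list alone). Among them XBP1 rose by 0.65 ± 0.05 and KRT18 by 0.23 ± 0.03. That list passed camera (adjusted p = 3.1e-04), a call that was lost (adjusted p = 0.15 with an estimated correlation). Of 8 basal markers 3 rose, CDH3 (3.33 ± 0.34), KRT17 (1.99 ± 0.35) and the myosin kinase gene MYLK (0.85 ± 0.03), and OXTR and CAV1 (-0.22 ± 0.06) fell (3 and 2 adjusted over the list alone), with no pass in camera (median 0.06, adjusted p = 0.16). That median rested on few genes, and was 0.0062 without p27-negative replicate 1, 0.10 without p27-negative replicate 3, 0.48 without the filter or with a minimum of 50 normalized counts and 0.60 in the FPKM table. KRT17 was at 2.61 without p27-negative replicate 1. The CAV1 call was lost under all 4 other scalings.

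Mesenchymal and matrix genes went both ways, 13 of 28 higher and 8 lower (14 and 8 adjusted over the list alone), with no pass in camera (median 0.58, adjusted p = 0.11). With quantile normalization that median was 0.22. The fibrillar collagen gene COL3A1 rose (1.78 ± 0.05) while CCN1, CCN2 and THBS1 (-1.56 ± 0.04) fell. Markers of other cell types moved beside them. Of 12 endothelial and stromal markers 7 were among the listed genes and 5 were tested. All 5 rose (5 adjusted over the list alone), with a median of 1.24, namely PDGFRA (2.63), COL3A1, VWF (1.24 ± 0.08), COL1A1 (1.22 ± 0.23) and CDH5 (0.45 ± 0.06). The list passed camera (adjusted p = 3.1e-04), and with an estimated correlation (adjusted p = 0.048), and COL3A1 and COL1A1 stand in both lists. Of 14 leukocyte markers 2 were tested, too few for a list test. ITGAM rose (90.2 ± 28.6 against 44.7 ± 19.9 normalized counts), a limma call lost without p27-positive replicate 1 (adjusted p = 0.096) or 3 (adjusted p = 0.070) or p27-negative replicate 2 (adjusted p = 0.12), while PTPRC, which encodes the common leukocyte antigen CD45, was at 15.8 ± 3.23 against 24.2 ± 9.26. Of 17 markers of breast stem cells and drug tolerance 8 rose and 5, AXL (-1.51 ± 0.10), BMP4 (-1.17 ± 0.05), GLI2, GLI1 and BMI1, fell (9 and 5 adjusted over the list alone), with no pass in camera (median 0.15, adjusted p = 0.20). CD44 (1.38 ± 0.05) and LGR5 (2.03 ± 0.09) were among those that rose.

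Stress and immediate early genes gave a mixed picture. Heat shock proteins fell in 12 of 20 cases, with a median of -0.52, and HSPA4L, DNAJB1 and DNAJB4 rose (12 and 5 adjusted over the list alone). HSP90AA1 fell from 94216 ± 1245 to 48991 ± 2186 normalized counts (-0.94 ± 0.02), and STIP1 (-0.79 ± 0.04) and HSP90AB1 (-0.68 ± 0.02) fell with it. Camera called the heat shock list (adjusted p = 1.1e-05), a call that was lost (adjusted p = 0.11 with an estimated correlation). Of 23 immediate early genes 13 fell and 6 rose (13 and 6 adjusted over the list alone), with a median of -0.59 and no pass in camera (adjusted p = 0.052). It passed camera with a pseudocount of 5, no filter, quantile normalization, upper-quartile rescaling, no trended prior or scaling to the library total (adjusted p = 0.010 to 0.045), without p27-positive replicate 2 (adjusted p = 0.045) or 3 (adjusted p = 0.031), and on recovered reads with edgeR (adjusted p = 0.0042) and DESeq2 (adjusted p = 0.00905). The count was 6 higher and 8 lower with scaling to the library total, and without p27-negative replicate 2 the median was -0.38. EGR1, KLF6 (-1.39 ± 0.10) and IER2 (-1.31 ± 0.10) fell. ATF4 targets rose in 14 and fell in 13 of 33 cases (15 and 14 adjusted over the list alone; median 0.14, camera adjusted p = 0.58), and passed with quantile normalization (adjusted p = 0.045). The mTORC1 inhibitor gene DDIT4 (2.74 ± 0.06), SESN2 (1.64 ± 0.07) and the serine synthesis gene PSAT1 (0.77 ± 0.03) rose, and the amino acid transporter gene SLC7A5 (-0.72 ± 0.03) fell. Scaled to the library total 15 ATF4 targets rose and 9 fell. Of 23 chaperone genes of the endoplasmic reticulum 15 fell and 5 rose (15 and 5 adjusted over the list alone; median -0.16, camera adjusted p = 0.24). PDIA6 (-0.39 ± 0.04) fell, and DNAJB9 (1.03 ± 0.10), XBP1, HERPUD1 (0.49 ± 0.05), SYVN1 and P4HB rose. With scaling to the library total 7 of these chaperone genes rose and 5 fell. Of 33 hypoxia and glycolysis genes 11 rose and 11 fell (12 and 11 adjusted over the list alone; camera adjusted p = 0.80), with a median of 0.01, a mean of 0.10 and a downward test, and with scaling to the library total 15 rose and 9 fell. The glycolytic genes PFKP (-0.76 ± 0.06), ENO1 (-0.56 ± 0.03) and LDHA (-0.51 ± 0.03) fell, and the mitophagy receptor gene BNIP3L (1.02 ± 0.08) rose.

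Histone genes went against the rest of the S-phase programme. Of 16 tested replication-dependent histone genes 9 rose and 3, H2AC20, H4C5 and H1-4, fell (9 and 3 adjusted over the list alone), with a median of 1.46. H2AC6 (2.89 ± 0.15), H2BC21 (2.76 ± 0.29), H2BC5 (2.20 ± 0.24) and H1-2 (1.47 ± 0.13) rose. Most transcripts of these genes end in a stem-loop without a poly(A) tail, so libraries selected for poly(A) hold only their tailed forms, and 16 of the 51 genes of the list were tested. Camera called the histone list (adjusted p = 0.00665), a call that was lost (adjusted p = 0.090 with an estimated correlation), also in the FPKM table (adjusted p = 0.37, median 0.45). The median was 0.22 without the filter and 2.40 with a minimum of 50 normalized counts.

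**Figure D2:**
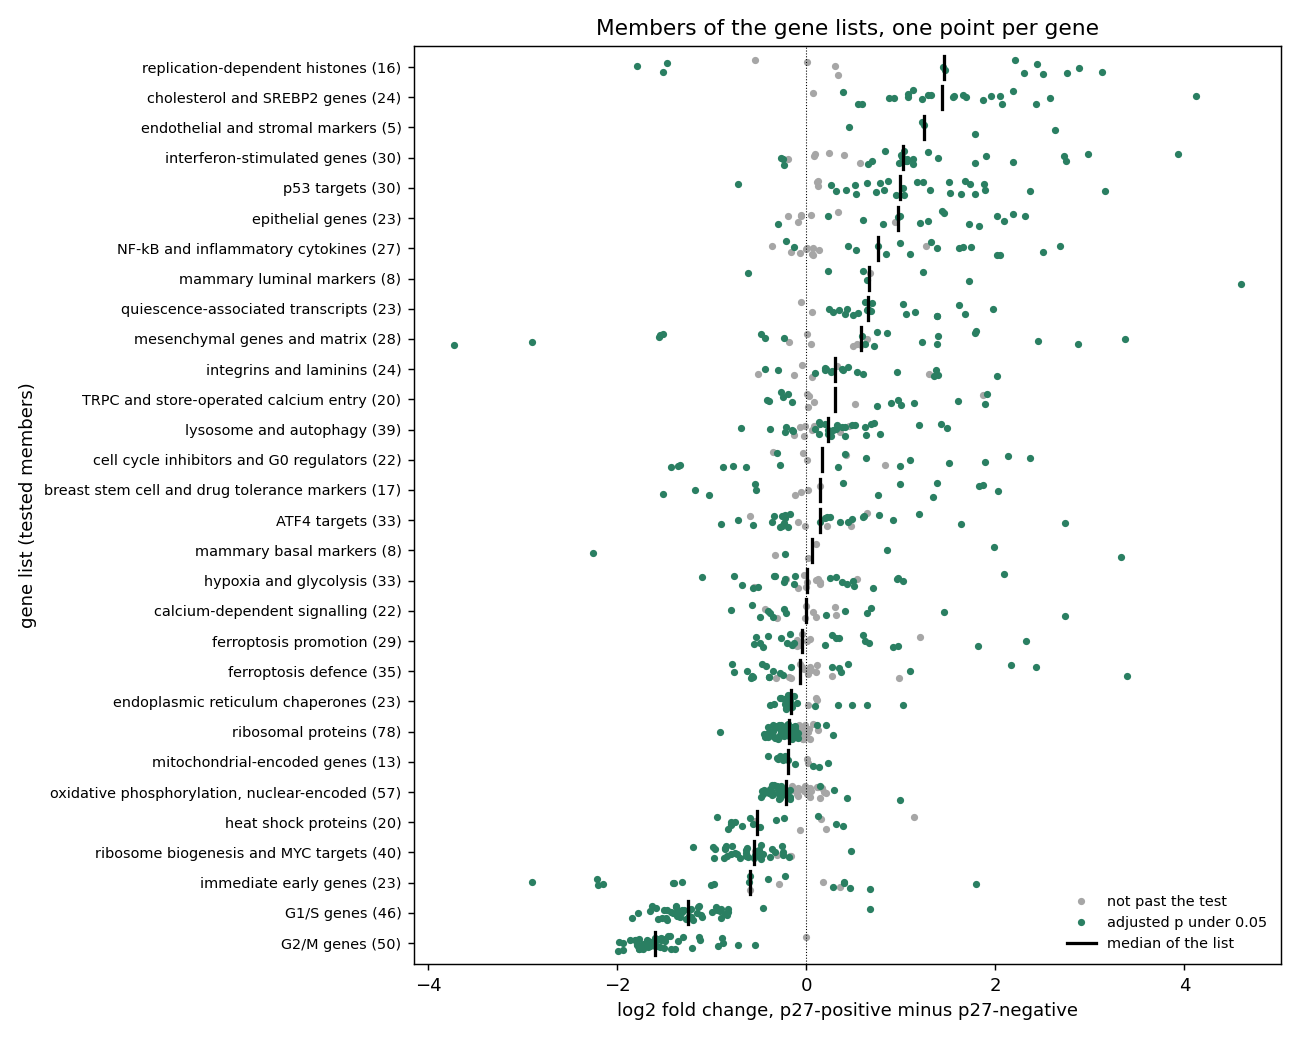
Log2 fold changes, p27-positive minus p27-negative, on the horizontal axis for each tested member of the 30 gene lists on the vertical axis, with the number of tested members in brackets. Green points passed the test over all genes, grey points did not, and black bars are list medians, from -1.60 for the G2/M genes to 1.46 for the histone genes. Small medians depend on scaling, since scaling to the library total moved the median of all genes by 0.13.

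More genes were detected in p27-positive cells. They numbered 20978 ± 169 of 22794 listed genes, against 19815 ± 94.1 in p27-negative cells. Reads of long noncoding RNA genes made up 1.04% ± 0.0221 and 0.825% ± 0.00882 of the reads assigned to listed genes. Of 2464 tested long noncoding RNA genes 429 rose and 111 fell, and of 12554 protein-coding genes 3556 rose and 4165 fell. Genes that overlap another gene, and antisense genes, are uncertain, since the strand setting of the counting is not given in the sources used here. Of the 154 genes that the rule names, 54 overlap a listed gene on the other strand, among them CDKN1B, SLC7A11, STARD4, ABAT, MAPK10, IFIT2, CCN2, SPC25, CCNA2, MCM7, ITPR2, ITPR3, THBS1, KRT8, KRT18, TP53INP1 and HSP90AA1. On their own strand 27 overlap a listed gene, among them ACSL4, SCN2A, IFIT2, FRK, CENPA, TOP2A, ATP2B4, FADS2, ODC1 and LDHA.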

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

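Of the tests in this part, those of exchanged labels, of a response to the plasmid and of scaling and of loss of RNA for the interferon-stimulated genes were chosen only after the result was seen, scaling to the library total was added after the data were seen, and the test of background for the large increases was added after that for the genes of low level was seen.

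A total of 291 genes had reads in every p27-positive library and none in any p27-negative library, a signal in genes mostly below the expression filter, against 48 genes of the reverse kind. Of the 291, 122 were protein-coding and 114 long noncoding, and 58 had at least 30 reads, against 2 of the reverse kind. Against a floor of 3 counts over the other group, CYP4F8 was 25.5-fold higher, the secretoglobin gene SCGB1D2 21.2-fold, the interferon-stimulated gene OAS2 19.7-fold and the chemokine gene CCL5 15.2-fold. NPAS4, an activity-induced transcription factor gene, was 9.90-fold lower against that floor. These genes were picked for having no reads in the other group. Of 6844 genes below the filter, limma without the filter called 303 higher and 59 lower.

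The excess of detected genes and of large increases was weighed as the first pattern. With every library thinned to 22216934 reads, the lowest p27-positive library still had 902 more detected genes than the highest p27-negative library, which argues against depth. For the large increases the authors' scaling cannot be told apart, since their share among called changes of at least 2-fold was 84.0% with scaling to the library total against 76.2%, a scaling that raised all genes by 0.13 and could only raise the share, and quantile normalization, which gives every library the same distribution, lowered it to 54.96%. Uniform background such as genomic DNA could account for part of the gain of genes of low level as a class. Processed pseudogenes below the filter gained 1.33 times as many reads per unit of length as protein-coding genes below it (95% bootstrap interval 0.755 to 1.94). Even background would give a ratio of 1, which this wide interval includes without showing it. Such pseudogenes share sequence with their parent genes, so reads of parent genes may be counted in them. The ratio therefore does not single out background. Of these pseudogenes 683 gained and 563 lost. Summed normalized counts in p27-positive cells were 1.13 times those in p27-negative cells for these pseudogenes and 1.66 times for these protein-coding genes. Whether background reaches the 52 reads of TRPC6 against 1 was not tested. For the large increases such background cannot be told apart, since their median gain per unit of length, 30.5 times that of those pseudogenes (20.8 to 53.03), compares genes selected for a large gain with genes below the filter, and a wider set of transcribed genes in p27-positive cells remains an open biological explanation.

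CDKN1B mRNA was lower in cells sorted as p27-positive, which raises the question of exchanged labels. That is argued against by the G2/M genes, with a median log2 fold change of -1.60 in the libraries labelled p27-positive and all 50 members below 0, the direction a cell cycle inhibitor gives. Scaling is argued against as the whole source, since the log2 fold change was -0.22 with scaling to the library total (95% interval -0.37 to -0.08). In the FPKM table it was -0.22 (SE 0.09) against -0.35 (SE 0.07) with the authors' size factors, and the call ended there as the size fell and the error grew. A p27 protein level set after transcription remains an open biological explanation that these libraries do not test.

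Interferon-stimulated genes had a median log2 fold change of 1.02 in p27-positive cells, which by the sort hold the reporter plasmid, and foreign DNA may induce such genes, though the list lost its camera call in another setting (adjusted p = 0.11 with an estimated correlation). Of the 30 tested members 21 were called higher, and a response to the plasmid cannot be told apart from one that goes with p27, since mock-transfected libraries are not analysed here. The authors' scaling is argued against as the source, since the lowest median over the 4 other scalings was 0.74, with quantile normalization. Loss of RNA from cycling cells cannot be told apart, since the median lay 0.99 above that of genes outside every list (95% bootstrap interval 0.64 to 1.09), which size factors hold near 0 in any case. Beside them OAS2 and CCL5 were read in p27-positive libraries alone.

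The 6 libraries can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 8385 called genes and the highest other split 0, so that 1 of 10 splits gave as many. For lists past camera the real split gave 17 and the highest other split 14, and 1 of 10 splits gave as many. Every other split mixes libraries of both groups, so it keeps part of the group difference and adds the rest to the spread. These counts therefore do not measure what chance gives, and do not rank gene calls against list calls.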

How the results depend on the processing

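All alternatives were planned except scaling to the library total, which was chosen only after the data were seen. With each library left out in turn, 7510 to 8074 genes were called (3496 to 3932 higher, 3989 to 4142 lower), 1250 to 1507 higher and 433 to 479 lower at least 2-fold, with 17 to 19 lists past camera (11 higher, 6 to 8 lower), a CDKN1B log2 fold change of -0.43 to -0.31 and a TRPC6 value of 3.20 to 3.999. The range was -0.087 to 0.0018 for GPX4 and -0.018 to 0.19 for the median of the cell cycle inhibitors. The replicate numbers did not pair the libraries (correlations of deviations 0.009, -0.0005 and 0.011), and with a replicate block 8395 genes and 18 lists were called, the mitochondrial-encoded list being the addition, and the call of no other list or named gene changed. At least 2-fold, 837 genes were higher with a minimum of 50, where fewer genes are tested, and quantile normalization gave 909 higher and 745 lower; the FPKM table gave 2832 lower genes. With an estimated correlation 11 lists passed (3 lower), and with fry, which compares with no other genes, 28 passed (19 higher). CDKN1B was at -0.22 in the FPKM table, and TRPC6 passed without the filter by limma (3.64), edgeR (5.15) and DESeq2 (5.49). A minimum of 50, quantile normalization, upper-quartile rescaling, the fit without a trended prior and the replicate block gave TRPC6 no value. GPX4 reversed with quantile normalization (0.12), upper-quartile rescaling (0.066), the FPKM table (0.084), scaling to the library total (0.084) and without p27-negative replicate 3 (0.0018). The direction of the list test, camera or where named fry, reversed for these lists, given with their medians. Cell cycle inhibitors reversed with no filter (0.0078), quantile normalization (0.018), upper-quartile rescaling (0.28), the FPKM table (0.091), scaling to the library total (0.30) and without p27-positive replicate 3 (0.12). Ferroptosis defence reversed with fry (-0.066), a minimum of 50 (-0.16), quantile normalization (-0.014), upper-quartile rescaling (0.046), scaling to the library total (0.064), edgeR (-0.068) and DESeq2 (-0.064), passing upward with fry and DESeq2. Hypoxia and glycolysis reversed with fry (0.0053), quantile normalization (0.10), upper-quartile rescaling (0.12), the FPKM table (0.13), no trended prior (0.0053) and scaling to the library total (0.14). With quantile normalization endoplasmic reticulum chaperones (0.01) and mitochondrial-encoded genes (-0.038) reversed. The cause of these changes was not tested. Among 154 named genes, 18 comparisons over 9 genes lost their call and 2732 kept their direction and side of the threshold. Depth limits TRPC6, with 52 reads in p27-positive and 1 in p27-negative libraries.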

Other observations

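The tests of this part used 6 lists written after the gene table was seen, each without the genes that prompted it, and adjusted over those 6 lists; some members, such as CDKN1A, SESN1, TXNIP, INSIG1 and FADS2, belong to lists already reported.

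Targets of the co-activator YAP and the TEAD transcription factors, which respond to cell spreading and tension, leaned lower in p27-positive cells. Beyond CCN1, CCN2 and ANKRD1, 13 of 23 were lower and 7 higher. With scaling to the library total 11 were lower and 8 higher, with a median of -0.20. AMOTL2 (-1.31 ± 0.05), THBS1 (-1.56 ± 0.04), AXL (-1.51 ± 0.10) and DLC1 (-0.97 ± 0.06) fell, and FSTL1 (0.58 ± 0.03) rose. Genes induced by ERK signalling fell more evenly, 16 of 19 with CCND1 the riser. They included the feedback inhibitor genes SPRY2 (-1.60 ± 0.07) and DUSP6 (-1.25 ± 0.06), and HMGA2 (-0.48 ± 0.03) and EMP1 (-0.48 ± 0.03). Of 21 FOXO targets 13 rose and 3, KLF6, IRS2 and ERBB3, fell, with CCNG2 (2.37 ± 0.06) and SESN1 (1.31 ± 0.08) among the risers. Of 18 genes of the list named for fatty acid synthesis 13 rose and GPAM and TMEM97 fell. The lipin gene LPIN1 (2.26 ± 0.07), INSIG1 (2.05 ± 0.09) and FASN, the fatty acid synthase gene (1.03 ± 0.03), rose. LPIN1, INSIG1 and TMEM97 do not encode enzymes that make fatty acids, so the list does not measure that synthesis alone.

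Genes of antigen presentation by MHC class I rose in 11 of 17 cases and CALR and PDIA3 fell, with HLA-B at 1.73 ± 0.07, HLA-C at 1.04 ± 0.06 and B2M at 0.77 ± 0.04 (median 0.71; camera adjusted p = 6.8e-05, and adjusted p = 0.023 with an estimated correlation). HLA genes share sequence, so their counts are uncertain, and with scaling to the library total 13 members rose and 1 fell. In the MXD and MYC network 6 of 11 rose and 4 fell, with no pass in camera (median 0.19, adjusted p = 0.26). MXD1, a repressor that competes with MYC, rose (2.15 ± 0.18) with MYCN (0.83 ± 0.09), while MYC (-0.60 ± 0.11) and MXD3 (-1.03 ± 0.14) fell.

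As hypotheses found and tested on the same data, lower output of YAP and TEAD and of ERK and higher output of FOXO factors may accompany the p27-positive state. The remaining YAP and TEAD targets had a median log2 fold change of -0.33 (camera adjusted p = 0.0034, and adjusted p = 0.036 with an estimated correlation), and the remaining ERK genes one of -0.60 (camera adjusted p = 5.8e-08, and adjusted p = 0.023 with an estimated correlation). The remaining FOXO targets had a median of 1.05 (camera adjusted p = 2.0e-04, and adjusted p = 0.027 with an estimated correlation). CDKN1A stands in both the FOXO and the p53 list, and TP53INP1, which prompted the FOXO list, is a p53 target. These values therefore do not separate FOXO output from that of p53. For the fatty acid synthesis list without SCD the median was 0.68 (camera adjusted p = 6.8e-09, and adjusted p = 0.016 with an estimated correlation). That list includes INSIG1 and other genes that do not make fatty acids. It therefore does not separate synthesis of fatty acids from the rise of sterol genes. RNA levels alone do not separate the output of YAP and TEAD, ERK and FOXO factors from a lower rate of division, which was not tested.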
